A study of Lotus japonicus with 16 samples.

How the data were processed

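Poly(A) RNA from whole shoots and whole roots of Lotus japonicus MG-20, a model legume accession, was sequenced as directional libraries with 150 bp paired-end reads, per the labels' protocols. Plants grew in hydroponics at 64 µM phosphate (sufficient P) or 6.4 µM phosphate (low P), and at 23 °C by day and 22 °C by night (favorable temperature) or 30 °C by day and 29 °C by night (high temperature). The 16 libraries fall into 8 groups of 2, one for each tissue, phosphate supply and temperature. Per the labels' protocols, 3 plants were pooled into 1 replicate and 5 replicates were grown per treatment, so the 2 libraries of a group are taken as separate pools. Groups and replicate numbers were read from the sample titles.

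The submitters' processing notes name Trimmomatic 0.39.2, FastQC 0.14.0, RSEM 1.3.3 and DESeq2 1.44.0, with no settings. The genome build and the annotation are not given in the sources used here. The analysis started from 4 tables, each the authors' own comparison of 2 groups of 1 tissue. Per the file headers, the columns are those of a DESeq2 result. The deposited base mean is the mean over libraries of gene counts divided by size factors. The deposited log2 fold change is on the log2 scale and comes with its standard error. The deposited Wald statistic is a score, and it equalled the log2 fold change over its standard error in every row, so the folds were not shrunken. The deposited p-value and adjusted p-value belong to that statistic. Every row had an adjusted p under 0.05 and an absolute log2 fold change of at least 1, so genes that did not change, or changed less, were not listed. Base means of genes listed in both tables of a tissue differed between the tables, which were therefore made on different libraries.

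No table holds counts or values per library. Read depth is therefore unknown, no test was made per gene from libraries, and the standard errors and adjusted p-values of single genes are the authors'. No replicate could be left out and no library could be compared with another. The design written before the data were examined provided for this case. Neither the files nor the labels state which group was the reference. "Up-regulated" was read as higher in the condition that a table's name gives last, which is low P in roots and high temperature in shoots, and every direction here depends on that reading.

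The number of genes behind the authors' adjustment was recovered as the adjusted p over the raw p of the top gene. It came to 20175, 20129, 20144 and 20438 genes for the 4 comparisons. These are called the genes tested here, and any genes left out before the adjustment are not counted. The rank behind the last listed adjusted p gave the least number of genes past 0.05 before the fold limit. On simulated tables of those sizes, the number tested was recovered exactly and the number past 0.05 to within 1 gene. The level of a gene in each condition was derived from its base mean and fold, for 2 libraries in each group. Where the lower level was under 1 normalised count, the fold is a fitted value and not a measured ratio.

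Genes listed in both tables of a tissue were tested for a difference between their 2 folds. The difference was divided by the root of the sum of the squared standard errors, referred to the normal distribution and adjusted by Benjamini-Hochberg over the shared genes. On simulated data for the 542 shared root genes, the test recovered 18.8%, 67.6% and 96.8% of differences of 1, 2 and 3 log2 units. For the 294 shared shoot genes it recovered 36.1%, 79.4% and 100% of such differences, and 2.8% of its calls were false. The simulations took the authors' standard errors as exact and did not apply the limits by which genes were listed. These shares therefore do not describe the test on genes selected by both of their folds. Genes in 1 table only were not tested, since their other fold is not listed. Directions in 2 tables were compared by two-sided Fisher's exact tests, adjusted over the 6 pairs of tables. Genes are not independent replicates, so these p-values describe the lists. Bootstrap and binomial intervals over genes likewise describe the lists and not the variation between libraries. No 2 tables share a library, but root and shoot tables cover the same treatment groups, and whether their libraries came from the same plants is not given in the sources used here. The exact tests do not allow for that.

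All 3958 gene identifiers matched a RefSeq gene table of assembly LjGifu_v1.2, which gives each only a locus number as its symbol. The 26 gene lists fixed beforehand, which search gene descriptions, could therefore not be scored. For the same reason the rule for named genes fell back to the 2 largest rises and 2 largest falls per comparison. Because the authors' build is not named, the reference served only for symbols and for which protein-coding genes neighbour each other, and no coordinates are given. The assembly is named for Gifu and the plants were MG-20. Whether gene order is the same in MG-20 was not checked. Alternatives were a stricter adjusted p, larger folds, base mean minimums, a Bonferroni limit, identical rows counted once, standard errors over 1 left out and no fold limit. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.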

Results

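Transcriptomes of Lotus japonicus roots and shoots were compared after 3 weeks at low or sufficient phosphate and at a favorable or a high temperature. The series addresses how a moderate rise in temperature acts on plants short of phosphorus. The data hold 4 comparisons, with 2 libraries in each group. In roots, low P was set against sufficient P at each temperature. In shoots, high temperature was set against the favorable one at each phosphate supply. Read depth per library is unknown. The median base mean of listed genes was 352 and 329 normalised counts in the root comparisons and 205 in each shoot comparison. "Rose" and "fell" stand for the authors' up-regulated and down-regulated genes, read as higher or lower at low P in roots and at high temperature in shoots. The tables do not state that orientation. The gene table used here gives no functions for these identifiers.

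**Figure D1:**
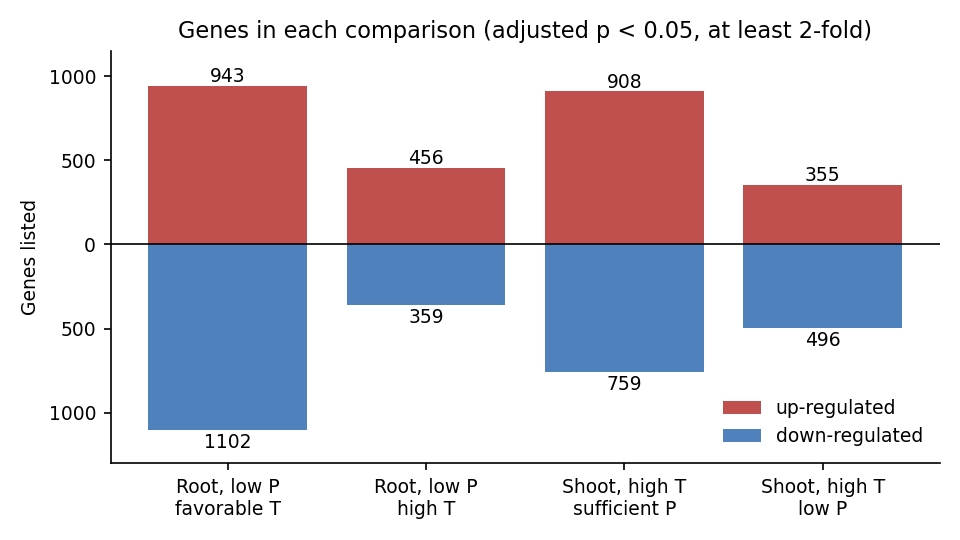
Number of genes listed as up-regulated (above 0) and down-regulated (below 0) in each of the 4 comparisons. The root comparison at the favorable temperature has the longest bars, with 943 and 1102 genes, and the root comparison at the high temperature has 456 and 359.

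Low P changed 2045 root genes at the favorable temperature, of which 943 rose and 1102 fell. These were 10.1% of the 20175 genes behind the authors' adjustment, called the genes tested here. LOC130721572 rose from about 3.34 to 5006 normalised counts, a log2 fold change of 10.55 (SE 0.63, DESeq2 adjusted p = 1.88e-58) in the authors' deposited table. LOC130749463 rose to 7817 normalised counts from a level fitted under 1, with a log2 fold change of 15.44 (SE 1.48) in the authors' deposited table. The largest falls were those of LOC130716628, from 107 normalised counts, and LOC130742748, from 99.9 normalised counts, both to levels fitted under 1. Their log2 fold changes in the authors' deposited table were -9.14 (SE 2.90) and -9.04 (SE 1.54). The median log2 fold change was 1.64 among genes that rose and -1.73 among genes that fell. At least 4-fold changes were seen in 326 genes that rose and 411 that fell. The lower level was under 1 normalised count for 29 genes that rose and 13 that fell.

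At the high temperature, low P changed 815 root genes, of which 456 rose and 359 fell. These were 4.05% of the 20129 genes tested. LOC130749463 again had the largest rise, to 3874 normalised counts from a level fitted under 1 (log2 fold change 14.38, SE 1.48, in the authors' deposited table). LOC130746340 had the next largest, reaching 229 normalised counts from a level fitted under 1 (10.30, SE 1.49, in the authors' deposited table). It had also risen at the favorable temperature, with a log2 fold change of 5.73 (SE 0.87) in the authors' deposited table. LOC130721572 rose by a log2 fold change of 10.14 (SE 0.76) in the authors' deposited table. The largest falls were those of LOC130730757, from 26.9 normalised counts, and LOC130723606, from 14.99 normalised counts, both to levels fitted under 1. The median log2 fold change was 1.58 among genes that rose and -1.57 among genes that fell.

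The 2 root comparisons shared 542 genes, against 82.8 for independent lists of these lengths among 20129 genes. Of these, 316 rose and 222 fell at both temperatures, and 4 changed in opposite directions (Fisher's exact test, two-sided, adjusted p = 3.66e-149 over 6 pairs of tables). Another 1503 genes were listed only at the favorable temperature and 273 only at the high temperature, which does not show that their responses differed. Among the 538 genes that went the same way, 409 had the larger absolute fold at the favorable temperature and 129 at the high temperature. The median absolute log2 fold change of these genes was 2.12 at the favorable temperature and 1.69 at the high temperature. Standard errors were larger at the favorable temperature (median log2 ratio, high over favorable, -0.24), and listing selects larger folds where errors are larger. The fold itself differed between temperatures for 34 of the 542 genes at an adjusted p under 0.05. Of these, 29 went the same way with the larger fold at the favorable temperature, 1 went the same way with the larger fold at the high temperature, and 4 went opposite ways. Genes listed with opposite signs pass this test almost by construction.

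The 4 root genes with opposite directions are named here because of that count, after their values were seen. LOC130749820 fell at the favorable temperature, with a log2 fold change of -2.44 (SE 0.38), and rose at the high temperature, with 2.36 (SE 0.39), in the authors' deposited tables. LOC130747247 likewise fell by 2.38 (SE 0.57) at the favorable temperature and rose by 2.30 (SE 0.47) at the high temperature on the log2 scale in the authors' deposited tables. LOC130738620 fell by 1.74 (SE 0.63) and rose by 1.85 (SE 0.59) on the log2 scale in the authors' deposited tables, both near the threshold. LOC130745279 rose at the favorable temperature (1.78, SE 0.37) and fell at the high temperature (-1.21, SE 0.31) in the authors' deposited tables.

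**Figure D2:**
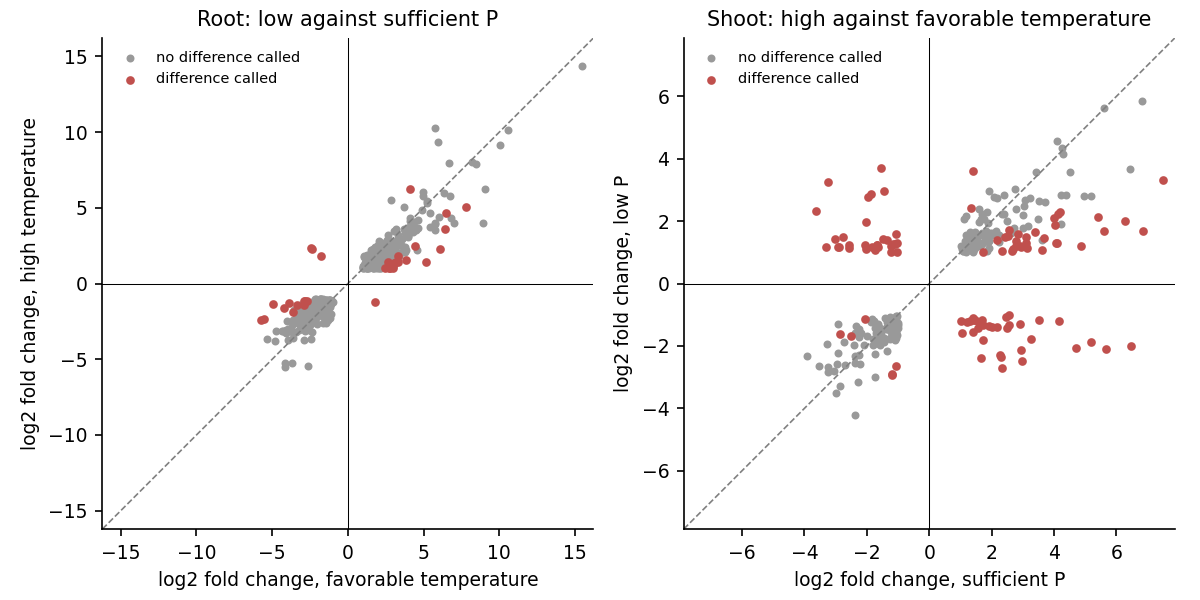
Authors' log2 fold changes of genes listed in both comparisons of a tissue, one point per gene, with the favorable temperature (root, left) or sufficient P (shoot, right) on the x axis and the other condition on the y axis. Red points are genes whose folds differed at an adjusted p under 0.05 (34 of 542 in roots, 103 of 294 in shoots), and the dashed line marks equal folds.

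High temperature changed 1667 shoot genes at sufficient P, of which 908 rose and 759 fell. With a base mean of at least 100 the balance turned, with 541 genes that rose and 573 that fell. The full list was 8.28% of the 20144 genes tested. The largest rise was shared by LOC130727573 and LOC130727575, each at 174 normalised counts from a level fitted under 1. Both had a log2 fold change of 9.86 (SE 1.86) in the authors' deposited table. All values of this pair were identical, so their reads cannot be assigned to one or the other. The largest falls were those of LOC130714592, from 17.8 normalised counts, and LOC130712220, from 15.7 normalised counts, both to levels fitted under 1. The median log2 fold change was 1.73 among genes that rose and -1.35 among genes that fell, and 370 genes rose at least 4-fold against 147 that fell as much. At least 3851 genes had an adjusted p under 0.05 before the fold limit, so 56.7% of them changed less than 2-fold. That share was 49.4% in shoots at low P, and 17.1% and 21.3% in roots at the favorable and the high temperature. The 10th percentile of the listed genes' standard errors was 0.17 and 0.20 in shoots (sufficient and low P). In roots it was 0.29 and 0.25 (favorable and high temperature). Smaller folds can pass where errors are smaller, so these shares do not compare the sizes of the responses.

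At low P, high temperature changed 851 shoot genes, of which 355 rose and 496 fell. These were 4.16% of the 20438 genes tested. LOC130723458 rose to 920 normalised counts from a level fitted under 1, with a log2 fold change of 12.39 (SE 1.46) in the authors' deposited table. LOC130725873 had the next largest rise, to 11.1 normalised counts. The largest falls were those of LOC130742350, from 76.9 normalised counts, and LOC130731803, from 59.9 normalised counts, both to levels fitted under 1. Both of these had risen in low-P roots at the favorable temperature, with log2 fold changes of 2.66 (SE 0.53) and 8.50 (SE 1.60) in the authors' deposited table. LOC130721572 and LOC130749463, which had large rises in low-P roots, fell in these shoots with log2 fold changes of -2.63 (SE 0.28) and -1.84 (SE 0.29) in the authors' deposited table.

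The 2 shoot comparisons shared 294 genes, against 70.4 for independent lists. At both supplies 134 of them rose and 96 fell (Fisher's exact test, two-sided, adjusted p = 1.08e-21). A further 34 rose at sufficient P and fell at low P, and 30 did the reverse. The fold differed between the supplies for 103 of the 294 genes at an adjusted p under 0.05. The 64 genes with opposite directions are among them by construction, since both of their folds had already passed. Of the other 39, 34 had the larger fold at sufficient P and 5 at low P. The genes listed in 1 shoot comparison only, 1373 at sufficient P and 557 at low P, were not tested for a difference.

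Genes of the low-P response of roots were also found among the temperature-responsive shoot genes. Of the 352 genes shared by the root comparison at the favorable temperature and the shoot comparison at sufficient P, 260 (73.9%) went the same way. This was more than the 49.6% given by the mix of directions (Fisher's exact test, two-sided, adjusted p = 3.21e-21). With the shoot comparison at low P, 48 of 219 genes (21.9%) went the same way, fewer than the 44.0% given by the mix of directions (adjusted p = 2.40e-13, Fisher's exact test). These shares rest on the orientation read for both tissues; with 1 tissue turned round, 92 of the 352 genes (26.1%) and 171 of the 219 (78.1%) would go the same way. As read, 124 of the 219 genes rose in low-P roots and fell in warm low-P shoots. With the root comparison at the high temperature, 81 of 163 genes (49.7%) went the same way as in shoots at sufficient P (adjusted p = 0.40, Fisher's exact test). With shoots at low P, 33 of 125 (26.4%) did (adjusted p = 1.76e-04, Fisher's exact test). With at least 4-fold changes, the overlaps with low-P shoots fell to 29 genes (favorable-temperature roots) and 17 genes (high-temperature roots). Of these, 24.1% and 23.5% went the same way (Fisher's exact p = 0.068 and 0.46). Root and shoot comparisons have treatment groups in common, though no library. The group at sufficient P and favorable temperature is the baseline of both comparisons in the first pair. The group at low P and favorable temperature is compared in roots and is the baseline in low-P shoots. For roots at the high temperature, the group at low P and high temperature is compared in both roots and low-P shoots. Sharing it would favor the same direction, yet 26.4% went the same way, against 40.7% given by the mix of directions. The group at sufficient P and high temperature is the baseline in those roots and is compared in shoots at sufficient P. Sharing it would favor opposite directions, and 49.7% went the same way, against 46.4%.

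**Figure D3:**
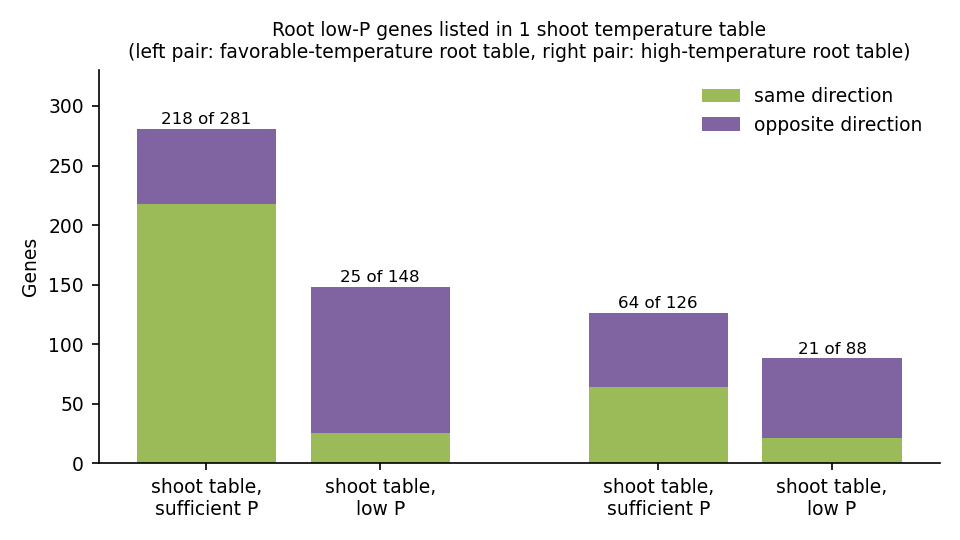
Number of root low-P genes that were also listed in only 1 of the 2 shoot temperature comparisons, split by whether they went the same way (green) or the opposite way (purple). For the root comparison at the favorable temperature, 218 of 281 went the same way as in shoots at sufficient P and 25 of 148 as in shoots at low P.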

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

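The tests of fold differences and of shared directions were planned; the split by genes in only 1 shoot comparison and the tests of technical explanations were chosen after the overlaps between tables had been seen. Results below were flagged because an effect differed between temperatures or between phosphate supplies.

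Low P changed fewer root genes at the high temperature, 815 against 2045, and 34 of 542 shared genes had different folds, 29 of them smaller at the high temperature. The high-temperature table has a stricter raw p limit, but 1806 genes of the favorable-temperature table meet that limit too, which argues against it as the whole cause. Selection of listed genes stays open as a cause of the smaller folds, because errors were larger at the favorable temperature. The median log2 ratio of standard errors, high over favorable, was -0.24 (95% bootstrap interval over genes -0.26 to -0.21). Of the 249 genes with an absolute log2 fold change of at least 2 at the high temperature, 51.4% had the larger fold at the favorable temperature when genes not listed there were counted against (exact 95% binomial interval 45.0 to 57.8), which does not decide it. For the 1503 genes listed only at the favorable temperature the precision at the high temperature is not listed, so a weaker low-P response of warm roots stays a hypothesis too.

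Of root low-P genes at the favorable temperature found in 1 shoot comparison only, 218 of 281 went the same way in shoots at sufficient P and 25 of 148 at low P, a gap of 60.7 percentage points (Fisher's exact test, two-sided, p = 9.06e-35). No gap given here was corrected for the mix of rises and falls in each list, which alone can give a gap. Over all genes shared with each shoot comparison, that mix gave 49.6% and 44.0% the same way. A turned sign in 1 shoot table alone is argued against. Of the genes in both shoot tables, 78.2% went the same way (exact 95% binomial interval 73.1 to 82.8). A turn of both tables of a tissue stays open, and by it every gap here would change sign. Weakly expressed gene models are also argued against. With a base mean of at least 100 and identical rows counted once, the gap was 63.6 percentage points. Duplicated gene models stay open, because counting identical rows once took at most 3 rows out of a table. Treatment groups shared by roots and shoots could give a positive gap with the favorable-temperature root table and a negative gap with the high-temperature one. The gap was 62.1 for genes listed in roots at the favorable temperature only. It was -34.3 for genes listed at the high temperature only (13 of 53 against 10 of 17 the same way, Fisher's exact p = 0.016). Of the 53 genes, 32 fell in roots and rose in shoots. Of the 17, 9 rose in both tissues and 6 rose in roots and fell in shoots, so their share may be what the mix gives. Both have the sign that shared groups could give in the orientation read here. A real effect or the mix of directions could give either sign too, so the signs do not tell these explanations apart. The whole high-temperature table had a gap of 26.9 (Fisher's exact p = 7.14e-05), the opposite of the sign that shared groups could give there. It includes genes listed at both temperatures (gap 54.4, Fisher's exact p = 2.15e-11). For those genes the shared groups pull both ways by unknown amounts, so the whole table does not decide. Shared groups therefore stay open, beside a supply-dependent change of phosphorus status in warm shoots, which may be an explanation and was not tested because the shoots' own response to low P was not analysed here.

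In shoots, 103 of 294 shared genes had different temperature folds at the 2 supplies, and 64 had opposite signs. In roots, 4 shared genes had opposite signs. Their differences of log2 fold changes, high minus favorable temperature, were 4.80 for LOC130749820 (SE 0.55), 4.67 for LOC130747247 (SE 0.74), 3.59 for LOC130738620 (SE 0.86) and -2.99 for LOC130745279 (SE 0.48).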

How the results depend on the processing

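No paired analysis was possible because the tables hold no values per library, and for the same reason no other count tool, low-count filter, pseudocount or left-out replicate was run. Rows without a gene description could not be left out, since none has one, and gene list alternatives were not run. Of 66 recomputed values, 14 could not change by construction. Of the other 52, 35 kept their direction and side of the threshold or stayed within 1.5 times, and none of these values reversed; but with a base mean of at least 100 the balance of shoot genes at sufficient P turned, from 908 up and 759 down to 541 up and 573 down. Requiring an absolute log2 fold change of at least 2 left 737 and 249 root genes and 517 and 199 shoot genes (favorable and high temperature, sufficient and low P). It left 174 genes shared by the root tables and 58 by the shoot tables. A Bonferroni limit over the listed rows left 862, 462, 1049 and 494 genes in the same order. This limit is more lenient than one over all genes tested. Without the fold limit, an alternative added after seeing the data, at least 3851 and 1682 shoot genes passed, by construction of the limit. An adjusted p under 0.01 left 21 root genes with different folds. A base mean of at least 100 left 57 shoot genes with different folds and 165 shared shoot genes. With at least 4-fold changes, root genes went the same way as in shoots at low P in 24.1% of 29 cases (favorable temperature, Fisher's exact p = 0.068) and 23.5% of 17 (high temperature, p = 0.46), where fewer genes were tested. Counting identical rows once and leaving out standard errors over 1, both also added later, changed none of the 4 table counts by over 1.5 times, but the second cuts the run of neighbouring genes given under the other observations from 11 to 6. With 2 libraries per group and unknown depth, genes missing from a table cannot be called unchanged.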

Other observations

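All tests in this part were chosen after the values had been seen, including the window of 12 genes, which was set to the run it describes. Listed genes that lie next to each other in the reference assembly often changed the same way. In low-P roots at the favorable temperature, 150 of 208 pairs of listed neighbours (72.1%) went the same way, against 50.3% with directions permuted. The shares were 79.4% of 34 pairs in roots at the high temperature, 77.4% of 137 pairs in shoots at sufficient P and 80.7% of 57 pairs in shoots at low P. The permutation p was 1e-05, the smallest that 100000 permutations can give, in each comparison except roots at the high temperature, where it was 4.5e-04 (adjusted 4.5e-04 over the 4 comparisons). With identical rows counted once, 148 of 206 pairs went the same way in low-P roots at the favorable temperature. Sharing of reads among similar neighbouring copies was not tested, so these shares do not show that neighbours were regulated together.

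The fullest stretch was a run from LOC130735503 to LOC130735511, in which 11 of 12 consecutive protein-coding genes fell in low-P roots at the favorable temperature. Their log2 fold changes in the authors' deposited table ran from -1.69 to -5.37 and their base means from 14.5 to 6450 normalised counts, and 1 of the 11 was also listed as down at the high temperature. The run has 9 members with an adjusted p under 0.01 and 6 with a standard error up to 1. LOC130735505 fell by 5.37 (SE 0.79) and LOC130735503 by 3.61 (SE 0.57) on the log2 scale in the authors' deposited table.

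Of 10000 random placements of the listed genes, 0% filled a window of 12 as far (at most 7 members), and 0.21% of permutations of direction with the places kept did, but the length was set to the run, so these shares do not decide. After they were seen, the fullest windows of every length from 5 to 30 genes were tested together. As extreme were 0.0999% of random placements, the least that 1000 draws can give, and 0.5% of permutations of direction. For the listed genes taken as they are, this argues against independent placement. Placements were drawn over all annotated protein-coding genes and not only those tested, which may leave random windows too empty. Listed neighbours shared directions in general, so the scan says little about this run in particular. The scan does not settle the run without its imprecise members. With standard errors up to 1 only, 6 members remain, random placements reach 7, and 1.6% reach 6 in a window of 12. Reads of one gene divided evenly among copies would give equal base means and equal folds. The base means, from 14.5 to 6450, already went against that. The folds also differed by more than their standard errors (Cochran's Q of 38.3, against a 95% point of 18.3), which adds little. Unequal sharing of reads among similar copies was not tested. Libraries of one group standing far apart may contribute: the members' standard errors had a median percentile of 94 among the 100 listed genes nearest in base mean, past the limit of 90 set for that explanation. After that value was seen, genes were rematched on the levels of both conditions, because a large fall leaves few reads in the lower group. The median percentile was then 86, short of the limit, so for the run as a whole this explanation stays open. Few reads are not a likely source of every large error. LOC130735507 had a base mean of 4153 with an SE of 1.24, and LOC130735508 939 with 1.31. LOC130735509 and LOC130738595, with SEs of 1.43 and 1.46, had base means of only 14.5 and 17.4.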
